A study of Mus musculus with 6 samples.

How the data were processed

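RNA was measured in 6 libraries of Podoplanin-sorted cells from orthotopic FC1199 tumours in Rosa-mTmG;Fabp4-Cre mice, 3 of the GFP and 3 of the Tomato fraction. Per the labels' protocols, libraries were built from 150 ng of total RNA with an Illumina TruSeq kit. The deposited values were raw read counts per gene, 1 table per library, with a column for both strands together and a column for each strand, per the file headers. Per the submitters' processing notes the authors used Trim Galore 0.4.3, STAR 2.5.2b and the mouse genome build GRCm38, with no roles given. The annotation release and any filter were not given in the sources used here.

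The column for both strands was analysed, because the strand columns held nearly equal counts (ratio 1.002 to 1.006 per library). Reads of overlapping or antisense genes therefore cannot be told apart. Genes of ribosomal proteins and of the mitochondrial genome share reads with pseudogenes, so their counts are uncertain. Each table had 49671 genes, of which 49412 matched the GENCODE M21 annotation of GRCm38 by identifier, and the 259 others held 0.008% of all counts. Names, gene types and coordinates (1-based) came from that annotation. The totals per library allow small differences to be seen for abundant genes, while a gene below 1 CPM rests on few reads.

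The labels do not say whether the replicates came from separate animals, so the p-values may measure only the spread between these samples. No replicates were duplicates: counts of libraries of the same group differed far beyond sampling noise (chi-square per degree of freedom 28.6 to 122). The correlation of log2 CPM was 0.986 to 0.99 within GFP, 0.978 to 0.99 within Tomato and 0.921 to 0.965 between them, and the first principal component, which held 75.6% of the variance, separated the fractions. Libraries of equal number deviated from their group means together across genes (correlations 0.403, 0.108 and 0.347, against -0.392 to 0.028 for unequal numbers). Since all 3 were above 0.1, the limit set beforehand, the numbers were taken to pair the libraries, from the data and not from the labels. This is weak ground, as 1 value is just above the limit and 3 libraries per fraction can match so by chance. The main fit had been set without a block, so its p-values leave out the pairing, and counts with the block are given beside it.

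GFP was compared with Tomato by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with robust estimation, TMM scaling, the filterByExpr filter and no block. P-values were adjusted by the Benjamini-Hochberg method over 15608 genes, with a threshold of 0.05. Standard errors were derived from the fold change and the F statistic. CPM are TMM-scaled and given as mean ± SD over 3 libraries. The common biological coefficient of variation was 0.158. Gene lists were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the 42 of 46 lists with at least 5 genes tested. Beside it stand camera with an estimated correlation and fry. With an estimated correlation camera takes its degrees of freedom from the libraries, and 6 libraries leave few. A list that does not pass that test is therefore not shown to be unchanged. The lists covered fibroblast types, other cells that the gate or the Cre driver could bring in, RNA quality, matrix, adhesion, signalling, metabolism, proliferation, stress and identity. Those of matrix, adhesion and axon guidance were written with knowledge of published work on these cells and are not blind to it.

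The samples, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the sort and driver genes, the 12 genes up and the 12 down with the largest change among protein-coding genes past the threshold with no overlap between the fractions and a mean of at least 10 CPM in the higher fraction, and in each list the 2 genes up and the 2 down with the smallest adjusted p. Of the 147 genes it gave, 145 are named, of which 20 lost their call without at least 1 library. The other 2, of which 1 lost its call in that way, are not reported here. A further 21 genes were named after their values were seen, namely Acta2, Tagln, Il6, Cxcl1, Dcn, Kdr, Vwf, Wt1, Muc1, Sox9, Epcam, Cdh1, Spint1, Fos, mt-Nd2, mt-Nd4, mt-Nd5, mt-Nd6, Malat1, Meg3 and Neat1.

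The alternatives tried were relative log expression, upper quartile and library size scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, estimation without robustness, the replicate number as a block, a single strand column, protein-coding genes alone, a threshold of 0.01, a test against a fold change of 1.5, and leaving out each library. A correction for transcript length and GC content, by offsets per library from splines with 4 degrees of freedom, was added after the data were seen, alone and with the block. It takes out any difference between the fractions that follows length or GC content, whether bias or real.

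The tests were tried on simulated counts for 15383 genes with the means and library sizes of this comparison, in 5 draws with 200 genes changed. The edgeR test recovered 37.9% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 95.5% of those changed 4-fold, and 10.4% of its calls were unchanged genes, above the nominal 5%. With the block 12.8% of calls were unchanged genes, with DESeq2 21.4% and with voom 9.12%. With no gene changed, edgeR called 0 of 15404 genes and camera called 1 list. The simulated genes were independent of each other, while the correlation estimated in the data was 0.88 for the acinar list, so this cannot show how often camera calls lists falsely. The simulation also had no replicate effect, and its shares of unchanged genes need not hold where 4505 genes were called. With a simulated length trend, where 15320 genes were tested, the correction lowered the unchanged genes called from 52 to 8.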

Results

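Gene expression was measured by RNA sequencing in 6 libraries of cells sorted from mouse pancreatic tumours. FC1199 cells, a mouse pancreatic cancer line, were injected into the pancreas of mice aged 8 weeks, and the tumours grew for 4 weeks. The hosts carried the Rosa-mTmG reporter, in which every cell makes the red protein Tomato until Cre recombinase switches it to GFP, and a Cre gene driven by the Fabp4 promoter. From the digested tumours, cells carrying Podoplanin were separated by reporter colour into a GFP and a Tomato fraction, with 3 libraries of each. Per the labels, the GFP fraction holds cancer-associated fibroblasts (CAFs) that descend from pancreatic stellate cells and the Tomato fraction holds CAFs of other origin. The total count per library ran from 33378377 to 42154933.

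The comparison asked how the GFP fraction differs from the Tomato fraction of the same tumour type. The gene that defines the gate was alike in both: Pdpn (chromosome 4, 143267431 to 143299564), which encodes Podoplanin, had 404 ± 35.5 CPM (counts scaled to library size; SD, n = 3) in GFP and 433 ± 19.6 in Tomato, a log2 fold change of -0.10 (GFP over Tomato, adjusted p = 0.481). Fabp4 (chromosome 3, 10204088 to 10208576), whose promoter drove Cre, was low in both fractions, at 17.1 ± 1.56 and 18.2 ± 0.907 CPM (log2 fold change -0.09, adjusted p = 0.551). Fibroblast genes were abundant in both. Col1a1, which encodes a chain of collagen I, was higher in GFP by 1.30 ± 0.21 on the log2 scale (SE; adjusted p = 0.00321), and the PDGF receptor gene Pdgfrb by 0.80 ± 0.11 (adjusted p = 0.00151). Thy1 was higher by 0.52 (adjusted p = 0.00888) and Pdgfra by 0.43 (adjusted p = 0.0418). The Pdgfra call was lost without any single library except Tomato replicate 1, with an adjusted p of up to 0.145, with library size as the only scaling (0.123) and after a correction for transcript length and GC content (log2 fold change 0.166, adjusted p = 0.227). Vim (log2 fold change 0.16) and Fap (0.22) did not pass, though Vim did with that correction and the replicate number as a block (0.27, adjusted p = 0.0481). Of the 8 sort and driver genes 4 were higher and none lower (also 4 and none adjusted over the list alone; camera adjusted p = 0.015, and 0.46 with an estimated correlation).

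**Figure D1:**
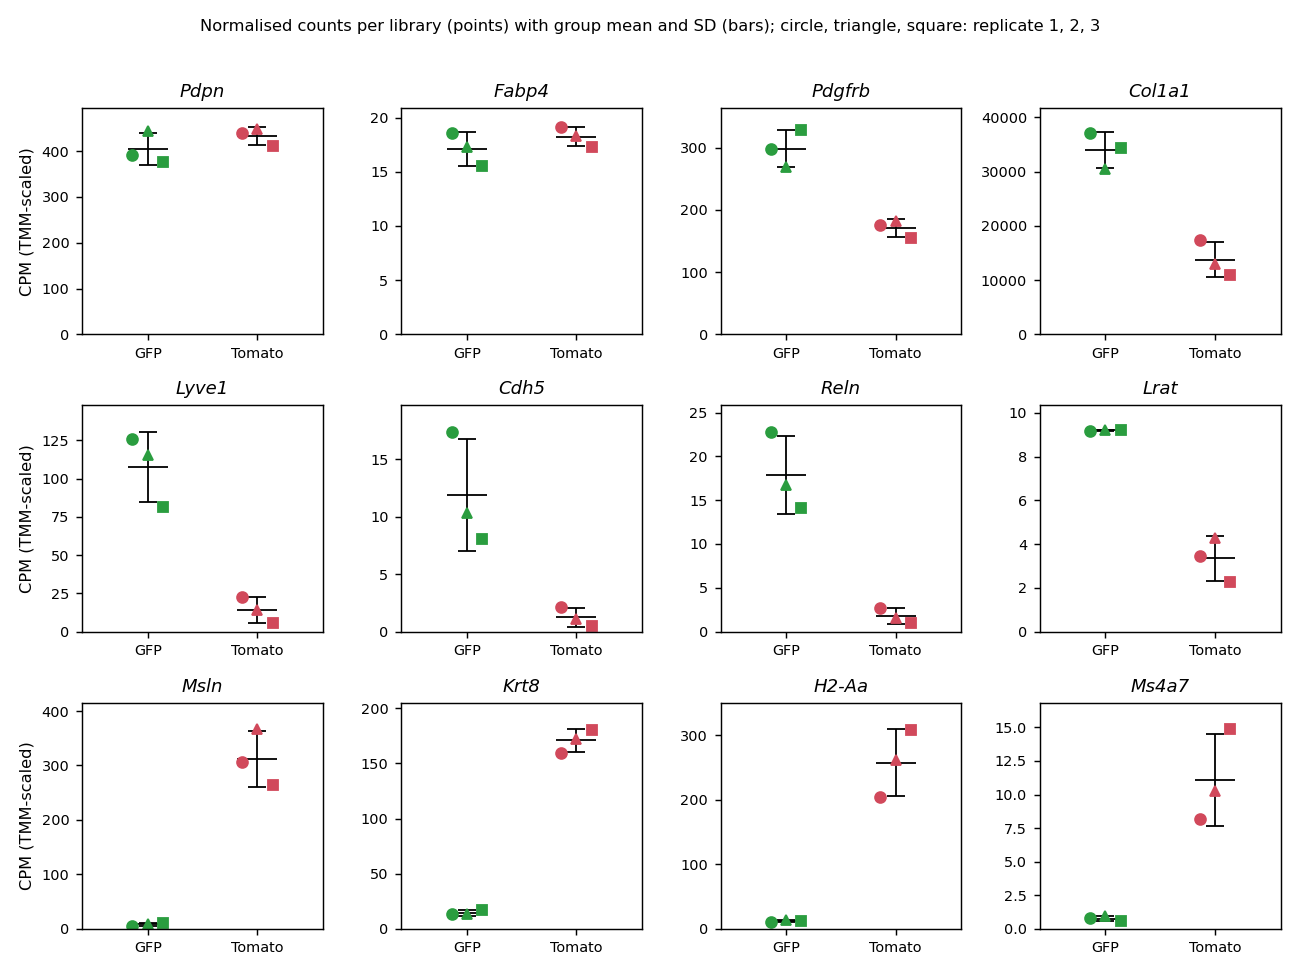
Normalised counts in CPM (vertical axes, linear from 0) for 12 genes in the GFP and Tomato libraries. Points are single libraries, with shapes for replicates 1 to 3, and bars are the group mean and SD (n = 3); Pdpn and Fabp4 overlap between the fractions, while Lyve1 averaged 108 against 14.2 CPM and Msln 8.16 against 312 CPM.

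Across the transcriptome, 2049 genes were higher and 2456 were lower in GFP among 15608 genes tested (edgeR, adjusted p under 0.05), and the lower set held the larger changes. At least 8-fold differences were found for 377 genes lower in GFP and for 15 genes higher in GFP. The fractions did not overlap for 48.6% of the genes tested, where chance gives 10%. Among protein-coding genes past the threshold with no overlap between the fractions and a mean of at least 10 CPM in the higher one, the largest rises in GFP were led by Reln, which encodes the secreted protein reelin (log2 fold change 3.33 ± 0.35, adjusted p = 0.00086, 17.9 ± 4.45 against 1.76 ± 0.882 CPM). They continued with the endothelial genes Cdh5 (3.23), Tie1 (3.13), Prox1 (3.02), Mmrn1 (2.99), Cldn5 (2.98), Lyve1 (2.92), Angpt2 (2.84) and Flt4 (2.81), and with Adgrg3 (3.02), Nts (2.79) and Afap1l1 (2.60). By the same limits the largest falls were those of Chil4, Chst4, Slpi, Muc16, Upk1b, Msln, Ccl17, Upk3b, Chil1, Il17re, Dcstamp and Krt14, with log2 fold changes from -6.27 to -4.96. Chst4, a sulfotransferase gene, stood at 0.246 ± 0.0886 CPM in GFP and 19.1 ± 4.35 CPM in Tomato (log2 fold change -6.26 ± 0.29, adjusted p = 8.89e-06). Chil4 had 26.9 ± 35.2 CPM in Tomato, a spread larger than its mean, and its call (adjusted p = 0.0316) was lost in 4 of the 6 fits that left out a single library, with an adjusted p of up to 0.0923. With the replicate number as a block, by edgeR, its log2 fold change was -6.33 (adjusted p = 4.22e-07).

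The counts of genes changed when a library was left out, which also lowers the number of samples. They were 920 higher and 1380 lower without GFP replicate 1, 833 and 1528 without Tomato replicate 2, and 1195 and 1551 without GFP replicate 3. With the replicate number as a block, 3137 genes were higher and 3256 lower. With library size as the only scaling the median log2 fold change of all genes tested was -0.16, against 0.00 with TMM scaling, and 22.7% of the calls were higher in GFP instead of 45.5%.

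Of 139 genes in the lists of the extracellular matrix, 68 were higher in GFP and 12 lower. Of 12 fibrillar collagen genes, 10 were higher and none lower (also 10 and none adjusted over the list alone), with a median log2 fold change of 0.92. Col12a1, which encodes a collagen on the surface of collagen I fibrils, was higher by 0.92 ± 0.10 (278 ± 19.8 against 146 ± 13.9 CPM, adjusted p = 0.000704) and Col27a1 by 0.91 ± 0.11 (adjusted p = 0.00109). With the length and GC correction and the block these were 0.46 and 0.41, and the list median was 0.52. Of 35 genes of matrix remodelling, 19 were higher and 2 lower (22 and 3 adjusted over the list alone). The protease gene Adamts4 (0.93, adjusted p = 0.000805) and the collagen prolyl hydroxylase gene P4ha3 (0.98, adjusted p = 0.00162) were among the former, and Mmp12, the macrophage metalloelastase gene, was lower (-3.29, adjusted p = 0.00019), as was the collagenase gene Mmp13 (-0.55, adjusted p = 0.0324). Of 19 elastic fibre genes 10 were higher and 1 lower (15 and 1 adjusted over the list alone), with Ltbp2 at 1.12 and Emilin1 at 0.69. The lower gene was Mgp, an inhibitor of calcification (-0.89, adjusted p = 0.0102). After the length and GC correction Mgp was at -0.32 (adjusted p = 0.08), and it passed at -0.32 with the block as well (adjusted p = 0.0114). Of 26 genes of matricellular proteins and glycoproteins 14 were higher and 2 lower (15 and 2 adjusted over the list alone). Thbs4 (1.39) and Comp (2.01) were higher, while Tgfbi (-2.83) and Matn4 (0.681 ± 0.167 against 5.47 ± 1.31 CPM) were lower. The camera adjusted p was 2.3e-08 for fibrillar collagen, 4.9e-05 for remodelling, 3.2e-05 for elastic fibres and 0.00054 for matricellular genes. With an estimated correlation between genes the adjusted p were 0.25, 0.41, 0.46 and 0.33.

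The 24 basement membrane genes went both ways, with 11 higher and 4 lower (12 and 4 adjusted over the list alone). Lama1 (1.52, adjusted p = 0.00113) and Col15a1 (1.34, adjusted p = 0.00086) were higher, and Lama5 (-2.75, adjusted p = 0.000789) and Npnt (-1.44, adjusted p = 0.00204), both expressed in epithelia, were lower. The camera adjusted p of the list was 0.039, and 0.7 with an estimated correlation. It was 0.395 without GFP replicate 3, 0.0515 without GFP replicate 1 and 0.713 after the length and GC correction (0.672 with the replicate number as a block as well). Of 23 proteoglycan genes 4 were higher, among them Vcan (247 ± 42.0 against 117 ± 31.0 CPM) and Bgn (0.80), and 3 lower, among them Srgn (-1.31), the proteoglycan gene of blood cell granules, and Prg4 (-1.25); 5 and 3 passed adjusted over the list alone. By camera the proteoglycan list had an adjusted p of 0.36. Macrophage and mesothelial markers, reported beneath, were lower in GFP in the same libraries in which matrix genes were higher, and endothelial markers were higher.

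Endothelial genes were higher in GFP. Of 7 lymphatic endothelial markers, 6 were higher and none lower (also 6 and none adjusted over the list alone), with a median log2 fold change of 2.81. Prox1, the transcription factor gene of lymphatic identity, had 27.0 ± 7.85 CPM in GFP and 3.31 ± 2.38 in Tomato (3.02 ± 0.52, adjusted p = 0.00687), and Flt4, the VEGF receptor gene of lymphatic vessels, had 54.4 ± 18.7 and 7.76 ± 2.28 CPM (2.81 ± 0.30, adjusted p = 0.00117). Sox18 (adjusted p = 0.000318, mean 11.5 against 3.81 CPM) and Pard6g (0.81, adjusted p = 0.000742) were also higher. Of 12 blood endothelial markers, several of them shared by all endothelium, 7 were higher and 1 lower (also 7 and 1 adjusted over the list alone). Tie1 (26.1 ± 4.25 against 2.97 ± 1.68 CPM) and Egfl7 (1.98, adjusted p = 0.000146) were higher and Esam was lower (-3.58, adjusted p = 0.000132). Kdr (37.9 ± 8.73 against 49.6 ± 9.06 CPM, -0.39, adjusted p = 0.151) and Vwf (below 1 CPM in both) did not pass. Kdr passed as lower with library size as the only scaling (-0.56, adjusted p = 0.0434) and with the length and GC correction and the block (-0.62, adjusted p = 0.029). By camera the adjusted p was 9.9e-08 for the lymphatic and 0.00032 for the blood endothelial list, and 0.22 and 0.33 with an estimated correlation.

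Of 19 stellate cell genes, 6 were higher and 2 lower in GFP (6 and 3 adjusted over the list alone). Reln and Lrat, the enzyme that esterifies retinol for storage (9.21 ± 0.0221 against 3.34 ± 1.01 CPM, 1.46 ± 0.22, adjusted p = 0.00225), were higher. Reln is also made by lymphatic endothelium. Gfap was below 1 CPM in both fractions and lower in GFP (-2.56, adjusted p = 0.00948), and the lipid droplet gene Plin2 was lower (-0.63, adjusted p = 0.0129), a call lost without GFP replicate 1 (adjusted p = 0.0527) and without Tomato replicate 2 (0.0538). The camera adjusted p of the list was 0.072, and 0.33 with an estimated correlation. It was 0.0421 without GFP replicate 1, 0.0478 without Tomato replicate 2, and 0.0425 without Tomato replicate 3. It was 0.0392 with library size as the only scaling, 0.04 with a filter of 1 CPM in 3 libraries, 0.0259 with a single strand column and 0.0472 after the length and GC correction. The fry test gave 0.0192.

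**Figure D2:**
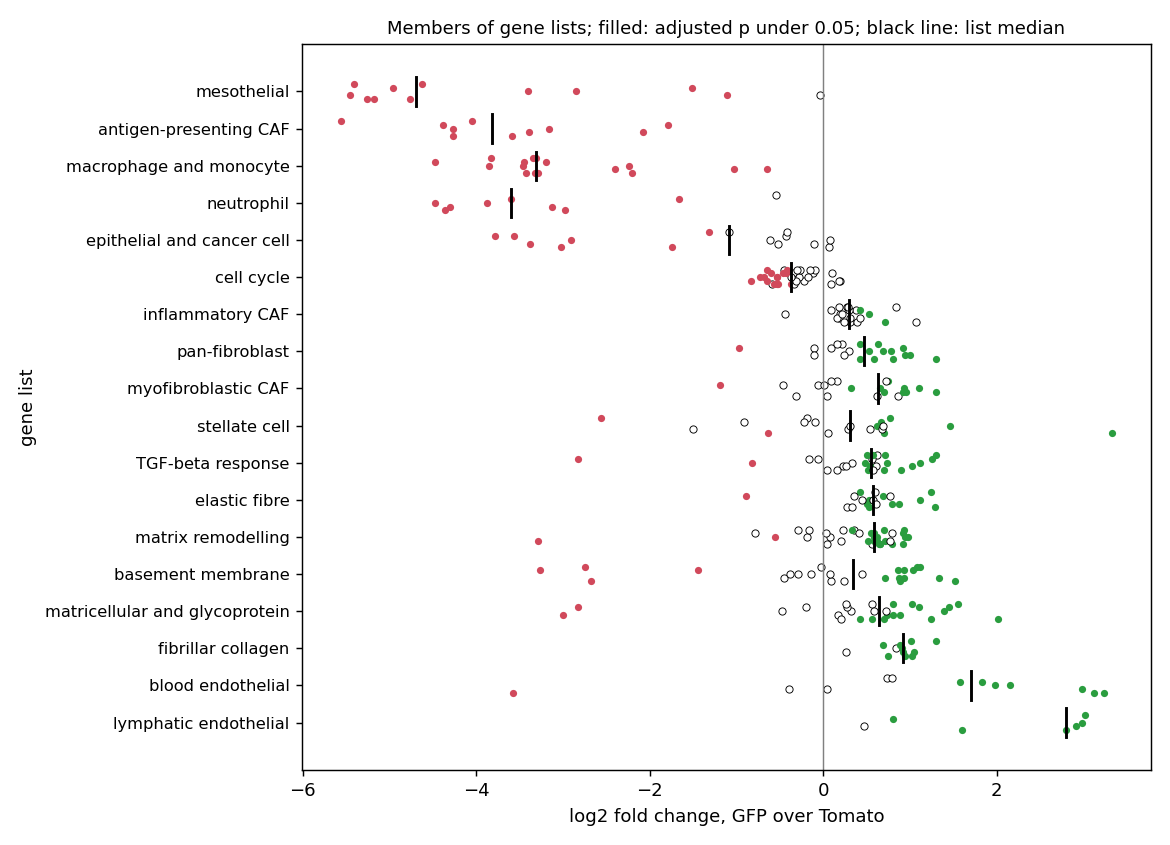
Log2 fold change (horizontal axis, GFP over Tomato) of the members of 18 gene lists (vertical axis). Points are genes, filled where the edgeR adjusted p was under 0.05, and black lines are list medians; medians ran from -4.69 for mesothelial genes to 2.81 for lymphatic endothelial genes.

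Mesothelial genes were lower in GFP. Of 12 such genes, which mark the lining of the body cavities, 11 were lower and none higher (also 11 and none adjusted over the list alone), with a median log2 fold change of -4.69. Msln, which encodes mesothelin, had 8.16 ± 3.34 CPM in GFP and 312 ± 51.5 in Tomato (-5.26 ± 0.34, adjusted p = 0.000166), and Upk3b 7.66 ± 5.85 and 276 ± 43.4 (-5.17 ± 0.63, adjusted p = 0.00177). Nkain4 (-2.84) and Krt14 (-4.96) had the smallest adjusted p, at 3.88e-05 and 1.8e-05. Wt1, which is also active in fibroblasts of the pancreas, had 103 ± 16.2 and 106 ± 4.34 CPM and did not pass (-0.03, adjusted p = 0.848). All 10 antigen-presenting CAF genes were lower (also 10 adjusted over the list alone), among them the MHC class II genes H2-Aa (12.3 ± 1.19 against 258 ± 51.9 CPM, -4.39 ± 0.17, adjusted p = 4.29e-06) and H2-Eb1 (-4.26, adjusted p = 4.29e-06) and the protease inhibitor gene Slpi (13.1 ± 8.87 against 618 ± 71.7 CPM). Of 15 epithelial and cancer cell genes, 7 were lower and none higher (8 and none adjusted over the list alone), led by the keratin genes Krt8 (14.4 ± 2.35 against 171 ± 10.5 CPM, adjusted p = 4.29e-06) and Krt18 (-3.02, adjusted p = 4.29e-06). Muc1 (0.07, adjusted p = 0.813) and Sox9 (0.08, adjusted p = 0.741) did not pass. Camera gave adjusted p = 8.3e-24 for the mesothelial, 2.1e-46 for the antigen-presenting CAF and 1.4e-16 for the epithelial list, each 0.1 with an estimated correlation.

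Markers of white blood cells were lower in GFP. All 16 macrophage and monocyte genes were lower (also 16 adjusted over the list alone), with a median log2 fold change of -3.31. Ms4a7 stood at 0.766 ± 0.184 against 11.1 ± 3.44 CPM (adjusted p = 0.000108) and Fcgr1, an Fc receptor gene, at 0.402 ± 0.0948 against 5.78 ± 2.11 (adjusted p = 0.00022). Apoe, which fibroblasts also express, was lower by less (-1.02, adjusted p = 0.00114). Of 9 neutrophil genes 8 were lower, among them S100a8 (-3.87) and Cxcr2 (-3.12), and of 5 dendritic cell genes 3 were lower, among them Itgax (-3.69) and Ccl22 (-5.06); 8 and 4 passed adjusted over the list alone. Camera gave adjusted p = 8.4e-22 for macrophages, 6.5e-09 for neutrophils and 0.00027 for dendritic cells, against 0.22, 0.13 and 0.13 with an estimated correlation. Few lymphocyte genes were detected: Il7r (-4.04) was lower among 2 T and NK cell genes tested, and Cd22 (-1.91) and Jchain (-2.65) among 3 B and plasma cell genes. Of 41 chemokine and cytokine genes, 16 were lower and 6 higher (17 and 6 adjusted over the list alone). With the length and GC correction and the block 16 were lower and 15 higher, and the median log2 fold change went from -0.24 to 0.047. The camera test stayed downward there (adjusted p = 0.00045). Cxcl13 (45.5 ± 6.60 against 173 ± 34.0 CPM, adjusted p = 0.00019) and Il16 (-1.59, adjusted p = 0.000776) were lower, and Cx3cl1 (0.69, adjusted p = 0.00105) and Il11 (0.84, adjusted p = 0.0083) were higher. The camera adjusted p of that list was 0.0022, and 0.22 with an estimated correlation.

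Of 20 myofibroblastic CAF genes, 9 were higher and 1 lower in GFP (11 and 1 adjusted over the list alone). Lrrc15 (122 ± 32.9 against 49.6 ± 9.21 CPM, 1.30, adjusted p = 0.00474) and Col12a1 were higher and Hopx was lower (-1.19, adjusted p = 0.0104), while the contractile genes Acta2 (476 ± 119 against 462 ± 88.7 CPM, 0.04, adjusted p = 0.89) and Tagln (-0.31, adjusted p = 0.464) did not pass. Of 21 inflammatory CAF genes, 3 were higher and none lower (2 and none adjusted over the list alone). With the length and GC correction and the block 13 were higher and none lower, and the median log2 fold change went from 0.29 to 0.54 (camera adjusted p = 7.9e-05). Has2, a hyaluronan synthase gene, was higher (0.53, adjusted p = 0.00889), and Lif was higher by 0.71 (adjusted p = 0.0103), a call just lost without Tomato replicate 2 (0.0503). Il6 had 1783 ± 382 and 1567 ± 199 CPM (0.19, adjusted p = 0.45) and passed as higher with the length and GC correction and the block (0.39, adjusted p = 0.019). Cxcl1 (0.39, adjusted p = 0.19) passed with the replicate number as a block, without that correction (0.38, adjusted p = 0.0307) and with it (0.67, adjusted p = 0.00196). Of 20 genes common to fibroblasts, 12 were higher and 1 lower (also 12 and 1 adjusted over the list alone), with S100a4 as the lower gene (-0.97, adjusted p = 0.0121; -0.38 and 0.164 with the length and GC correction and the block), and Dcn, which encodes decorin, was at 7750 ± 1241 and 8306 ± 1247 CPM (-0.10, adjusted p = 0.695). Camera gave adjusted p = 0.0016 for the myofibroblastic, 0.023 for the inflammatory and 6.2e-05 for the common fibroblast list, against 0.5, 0.7 and 0.46 with an estimated correlation. The inflammatory call was also lost without GFP replicate 1 (0.0515), GFP replicate 2 (0.0694) or Tomato replicate 3 (0.104).

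Among signalling genes, 13 of 26 genes of the TGF-beta response were higher and 2 lower (15 and 2 adjusted over the list alone). Ltbp2 was higher, and Id1, a target of BMP signalling (-0.82, adjusted p = 0.00339), and Tgfbi were lower. Of 14 Notch pathway genes 5 were higher and none lower (6 and none adjusted over the list alone), among them Notch4, a receptor gene of endothelium (1.47, adjusted p = 0.00127), and Heyl (0.88, adjusted p = 0.00889). Camera gave adjusted p = 0.00012 for the TGF-beta and 0.0082 for the Notch list, and 0.22 and 0.41 with an estimated correlation. The Notch call was lost after the length and GC correction (0.0749) and just kept with the block as well (0.049). Of 35 Wnt and BMP genes 5 were higher and 5 lower (also 5 and 5 adjusted over the list alone). The Wnt antagonist genes Sfrp1 (1635 ± 257 against 740 ± 62.9 CPM, 1.14, adjusted p = 0.00106) and Nkd2 (1.10, adjusted p = 0.000785) were higher, and Rspo1, which strengthens Wnt signalling (-1.51, adjusted p = 0.000399), and Bmp4 (-1.46, adjusted p = 0.00281) were lower. Of 24 vessel growth factor genes 4 were higher and 2 lower (also 4 and 2 adjusted over the list alone), with Angpt2 and Angpt4 (0.85, adjusted p = 0.0129) higher, and Pdgfc (-0.39, adjusted p = 0.0333) and Fgf1 lower, the latter at 38.2 ± 3.37 against 211 ± 41.8 CPM (-2.47, adjusted p = 4.69e-05).

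Adhesion and guidance genes went both ways. Of 33 integrin and focal adhesion genes 13 were higher and 6 lower (17 and 6 adjusted over the list alone). Itga9 (0.84, adjusted p = 0.00126) and Itga1 (0.78, adjusted p = 0.00234) were higher, and Itga3 (-2.11, adjusted p = 3.44e-05) and Itga7 (-2.25, adjusted p = 0.00154), both laminin receptor genes, were lower. With the length and GC correction and the block 12 genes of the list were higher and 9 lower, with Itga9 at 0.53, Itga1 at 0.40, Itga3 at -2.38 and Itga7 at -2.40. Of 25 cell-cell adhesion genes 7 were higher, among them Cdh5 and Cdh13 (2.20), and 6 lower, among them Esam and Cadm1 (-1.82); 9 and 6 passed adjusted over the list alone. Of 40 axon guidance genes 19 were higher and 6 lower (22 and 8 adjusted over the list alone). With the length and GC correction and the block 15 were higher and 13 lower, and the median log2 fold change went from 0.42 to 0.17. Nrp2 (39.9 ± 7.37 against 16.2 ± 1.66 CPM, 1.30, adjusted p = 0.000663) and Sema7a (0.95, adjusted p = 0.00325) were higher, and Plxnb1 (-2.02) and Sema4a (-2.23) were lower. The camera adjusted p of the guidance list was 0.034, and 0.65 with an estimated correlation; it was 0.0515 without GFP replicate 1, 0.0798 without Tomato replicate 3 and 0.789 after the length and GC correction. Of 36 position and lineage transcription factor genes 12 were higher, among them Meox1 (10.8 ± 0.411 against 3.63 ± 1.07 CPM, 1.58, adjusted p = 0.00155) and Tbx3 (1.11, adjusted p = 0.00105), and 5 were lower, among them Barx1 (29.0 ± 10.2 against 88.7 ± 13.8 CPM, -1.62, adjusted p = 0.00655) and Isl1 (-1.86, adjusted p = 0.00688). Those counts were the same adjusted over the list alone.

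Cell cycle genes were lower in GFP: 16 of 35 passed as lower and none as higher (20 and none adjusted over the list alone), with Mcm7 at 32.0 ± 0.813 against 47.3 ± 3.67 CPM (-0.56, adjusted p = 0.00341) and Nusap1 at -0.72 (adjusted p = 0.00576). Of 29 interferon response genes 10 were lower and none higher (12 and 1 adjusted over the list alone), with Gbp2 at -1.07 (adjusted p = 0.00135) and the immunoproteasome gene Psmb8 at -0.80 (adjusted p = 0.00119). Camera gave adjusted p = 0.00087 for the cell cycle and 0.016 for the interferon list, and 0.7 for each with an estimated correlation. The interferon call was lost without Tomato replicate 1 (0.133), without GFP replicate 3 (0.126) and after the length and GC correction (0.0606). Of 32 hypoxia and glycolysis genes 12 were lower and 3 higher (15 and 4 adjusted over the list alone). Aldoc (-2.93, adjusted p = 0.00427) and Egln3 (20.7 ± 3.50 against 91.2 ± 43.3 CPM, adjusted p = 0.00449) were lower, and Hk2 (0.72, adjusted p = 0.00526) and Eno2 (0.44, adjusted p = 0.0349) were higher. The camera adjusted p of that list was 0.053, and 0.00047 with the replicate number as a block (0.67 with the block and an estimated correlation); it was 0.0131 without Tomato replicate 1, 0.00683 without Tomato replicate 2 and 0.0123 without GFP replicate 3. All 16 macrophage genes, 8 of 9 neutrophil genes and 11 of 12 mesothelial genes were lower in the same GFP libraries, and whether the falls in these 3 lists lie within the fibroblasts was not tested.

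Of 18 acinar genes 1, the trypsinogen gene Try5 (-1.18, adjusted p = 0.0289), was lower and none higher (none adjusted over the list alone), with a median log2 fold change of -1.03 and camera adjusted p = 0.011, or 0.7 with an estimated correlation. It was 0.0637 with library size as the only scaling and 0.0631 after the length and GC correction. With the replicate number as a block 17 of the acinar genes were lower (camera adjusted p = 6.3e-06, or 0.67 with an estimated correlation), and 5 with the length and GC correction as well. Of 11 pericyte and smooth muscle genes 4 were higher, among them Mcam (0.72) and Notch3 (0.89, and 0.36 with adjusted p = 0.162 after the length and GC correction), and 1, the channel gene Kcnj8 (-0.82), was lower. Of 5 adipocyte genes Lpl, which encodes lipoprotein lipase, was higher (0.80, adjusted p = 0.00514) and Pnpla2 lower (-0.56, adjusted p = 0.016), the latter lost without Tomato replicate 2 (0.0613). Of 7 Schwann cell genes 2 were lower, Mbp (-1.54) and Erbb3 (-1.84), and 1, Cdh19 (0.91, adjusted p = 0.0354), was higher. Among 3 erythroid genes Alas2 was lower (-3.54), and none of 3 islet genes passed. Adjusted over the list alone 5 pericyte genes were higher and 3 Schwann cell genes lower, and the other counts of these 5 lists were the same.

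Of 20 genes induced by tissue dissociation 4 were higher, among them Jund (0.38) and Klf6 (0.44), and 2 lower, Atf3 (-0.58) and Hspb1 (191 ± 10.6 against 363 ± 8.58 CPM, -0.92), while Fos had 4917 ± 228 and 4010 ± 805 CPM (0.29, adjusted p = 0.209) and passed as higher with the length and GC correction and the block (0.47, adjusted p = 0.0298). Of 7 genes of the mitochondrial genome 2, mt-Co1 (-0.75, adjusted p = 0.0172) and mt-Nd1 (-0.46, adjusted p = 0.0473), were lower and none higher (3 and 2 adjusted over the list alone). It was otherwise with the length and GC correction and the block, where 4, namely mt-Nd2 (0.76), mt-Nd4 (0.63), mt-Nd5 (0.71) and mt-Nd6 (1.13), were higher and none lower. The list median was then 0.63 and the upward camera adjusted p 0.013, against 0.95 with neither. Without the correction mt-Nd2 passed as higher without GFP replicate 3 (adjusted p = 0.0348), mt-Nd5 without Tomato replicate 3 (0.00565) and mt-Nd6 without GFP replicate 3 (0.0469) or Tomato replicate 3 (0.0237). After the correction alone mt-Nd1 was at 0.05 (adjusted p = 0.783). Of 32 lipid metabolism genes 5 were higher, among them Dgat1 (0.54), and 6 lower, among them Fabp5 (-1.72), and of 22 cholesterol synthesis genes 1 was higher and 1, Sc5d (-0.36), lower. Of 24 p53 target genes 4 were higher, among them Gdf15 (0.92) and Zmat3 (0.76), and 2 lower, Perp (-3.80) and Fas (-0.66). Of 24 genes of the unfolded protein response Sel1l was higher (0.52) and Chac1 (-1.85) and Dnajb9 (-0.45) were lower. Of 14 Hedgehog pathway genes 3 were higher, among them Gli3 (0.81) and Sufu (0.46), and 1, Foxf1 (-1.22), was lower. Adjusted over the list alone 7 lipid metabolism genes were higher and 7 lower, and no cholesterol synthesis gene passed, while the counts of the dissociation, p53 target, unfolded protein response and Hedgehog lists were the same.

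Several calls of small size were lost when a library was left out. The call of Cdh19 was lost whichever library was left out (highest adjusted p 0.101, without Tomato replicate 3), with a log2 fold change of 0.817 to 0.996. Apart from Pdgfra, Chil4, Plin2, Lif and Pnpla2, given above, calls lost in 5 of the 6 fits included those of Jund (0.123, without Tomato replicate 2), Klf6 (0.129, without GFP replicate 1), Mmp13 (0.103, without GFP replicate 2), Pdgfc (0.115, without Tomato replicate 2) and Sc5d (0.129, without GFP replicate 1). In 4 fits the calls of Eno2 (0.12, without Tomato replicate 2), Gli3 (0.0799, without GFP replicate 1), Try5 (0.0715, without Tomato replicate 1) and mt-Nd1 (0.15, without GFP replicate 1) were lost, and in 3 that of Atf3 (0.0686, without GFP replicate 3). Those of Sel1l (0.061, without GFP replicate 1), Sufu (0.064, without Tomato replicate 2) and mt-Co1 (0.0678, without GFP replicate 1) were lost in 2 fits, and that of Foxf1 (0.0504, without Tomato replicate 2) in 1. The length and GC correction ended the calls of Sel1l (log2 fold change 0.30, adjusted p = 0.0528), Dnajb9 (-0.24, 0.058), Gli3 (0.49, 0.0611), Jund (0.31, 0.0888), Atf3 (-0.41, 0.115), Mmp13 (-0.37, 0.189), Try5 (-0.72, 0.14) and mt-Co1 (-0.38, 0.0681). With the block added those of Mmp13 (0.141), Try5 (0.0962) and mt-Co1 (0.0511) still did not pass. With library size as the only scaling the calls of Cdh19 (0.066), Klf6 (0.102), Jund (0.143), Sufu (0.0534) and Eno2 (0.0919) were lost.

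In all, camera placed 24 of 42 lists past the threshold with its preset correlation, 14 higher and 10 lower in GFP. None passed with an estimated correlation, where the lowest adjusted p was 0.1 and 9 lists had an unadjusted p under 0.05. That test has few degrees of freedom with 6 libraries, so its outcome does not show that the lists are unchanged. By fry, which tests each list by itself, 19 lists moved on balance in 1 direction, the stellate and Schwann cell lists among them, while 7 of the 24 did not pass. In 6 lists the median, the mean and the test differed in sign. The median and mean log2 fold changes were 0.35 and -0.002 for integrin and focal adhesion, 0.26 and -0.012 for the mitochondrial genome, 0.05 and -0.07 for p53 targets, 0.07 and -0.011 for the unfolded protein response and 0.22 and -0.008 for transcription factors, each with an upward test, and 0.14 and 0.045 for cell-cell adhesion, with a downward test. With the replicate number as a block some counts rose by over 1.5 times and by at least 2 genes. The genes called lower rose from 1 to 17 in the acinar, 1 to 7 in the cholesterol synthesis, 16 to 25 in the cell cycle, 5 to 8 in the transcription factor, 2 to 4 in the stellate cell and 2 to 4 in the p53 target list. Those called higher rose from 10 to 17 in the elastic fibre, 3 to 8 in the inflammatory CAF, 5 to 11 in the Wnt and BMP, 4 to 9 in the vessel growth factor, 4 to 9 in the dissociation and 5 to 9 in the Notch list. They also rose from 5 to 8 in the lipid metabolism, 3 to 5 in the Hedgehog, 1 to 3 in the unfolded protein response and 0 to 2 in the interferon list. Leaving out a library brought 6 of the other 18 lists past the threshold: the stellate cell list and the hypoxia and glycolysis list, each in the 3 fits given with it, integrin and focal adhesion without GFP replicate 2 (adjusted p = 0.00309), pericyte and smooth muscle without GFP replicate 1 (0.0421) or GFP replicate 2 (0.014), Schwann cell without Tomato replicate 3 (0.0347) and dissociation stress without Tomato replicate 1 (0.0155). The B and plasma cell list had too few genes to be tested with all 6 libraries and at least 5 in some of these fits. It passed as lower without GFP replicate 1 (0.0207), GFP replicate 2 (0.0225), Tomato replicate 2 (0.0418) or Tomato replicate 3 (0.0166). It did not without GFP replicate 3 (0.0548). Other alternatives also brought lists past the threshold. With library size as the only scaling these were the pericyte and smooth muscle (0.0462) and transcription factor (0.0404) lists. Integrin and focal adhesion passed with a filter of 1 CPM in 3 libraries (0.0418) and with a single strand column (0.0406), and hypoxia and glycolysis with the latter (0.03). After the length and GC correction the Schwann cell (0.04), hypoxia and glycolysis (0.0352) and mitochondrial genome (0.0129) lists passed. With the block added hypoxia and glycolysis (0.000233), vessel growth factors (0.0467) and dissociation stress (0.0475) did.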

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

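The length and GC correction, and the estimated correlation with the replicate block, were chosen after the results were seen, and the other alternatives before; the cause was not tested unless stated. With library size as the only scaling there were 1128 genes higher in GFP and 3851 genes lower in GFP. A test against a fold change of 1.5 called 216 and 936, and a threshold of 0.01 called 578 and 1083, both being stricter by construction. With the replicate block 3137 genes were higher and 3256 lower, and 4493 of the 4505 calls were shared in direction. The block brought Cxcl1 and the hypoxia and glycolysis list past the threshold and changed no other call among the 168 genes examined and the camera tests of lists. Leaving out 1 library, which lowers the number of samples, gave 833 to 2392 genes higher, 1380 to 2793 lower and 23 to 27 lists, out of 43 or 44 tested there. Under the other scalings, filters and tools the counts of genes stayed within 1.5 times. With an estimated correlation between genes 0 lists passed, and also 0 with the replicate block. The few degrees of freedom of 6 libraries, fewer still with the block, make that test hard to pass. After the length and GC correction 1551 genes were higher and 1890 lower, of which 1163 and 1644 were the same genes as without it. The fold change of mt-Nd1 turned from -0.46 to 0.05, and to 0.044 with the block. Of 168 genes examined, 22 of the 149 past the threshold lost it without at least 1 library and none of these 149 turned direction. DESeq2 lost 1 of the calls, library size scaling 7, a single strand column 3 (S100a4 at adjusted p 0.0749, Jund 0.0509 and Neat1 0.0537) and the length and GC correction 14, that of mt-Nd1 included.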

Other observations

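The splits of the samples were planned, and each test of an explanation was chosen after the result it bears on had been seen. Of 3 gene families chosen after the data were seen, most members were lower in GFP, though fewer of them were after the length and GC correction. Of 79 ribosomal protein genes 70 were lower and none higher (median log2 fold change -0.54), of 37 genes of complex I of the respiratory chain 27 were lower (-0.49) and of 18 proteasome core genes 13 were lower (-0.42). The camera p was 2.3e-12, 3.2e-07 and 0.00011, and 0.33, 0.34 and 0.25 with an estimated correlation. With the length and GC correction and the replicate block 13, 7 and 6 of them were lower, with medians of -0.20, -0.09 and -0.09. Short transcripts were lower in GFP in general: the Spearman correlation of fold change with transcript length, across 15576 genes that are not independent replicates, was 0.33. Of 861 long noncoding RNA genes 95 were higher and 58 lower (median log2 fold change 0.16, and -0.004 with library size as the only scaling), and 171 and 46 with the length and GC correction and the block (0.37); the camera p was 0.052, and 0.13 with an estimated correlation. The imprinted Meg3 had 141 ± 13.3 against 47.3 ± 12.0 CPM (1.58, adjusted p = 0.000671). Malat1 was higher by 0.59 (adjusted p = 0.00805), and Neat1 by 0.54 (adjusted p = 0.0214), or 0.06 (adjusted p = 0.61) with the length and GC correction and the block; the Neat1 call was lost without GFP replicate 1 (0.0559) and Tomato replicate 2 (0.074).

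Keratin and MHC class II genes were lower in GFP. Ductal or cancer epithelial cells as the whole source of the keratins were examined with the 11 other members of the epithelial list. These had a median log2 fold change of -0.515 (quartiles -1.199 and -0.259), where the 4 keratins had -3.20. Their median excess in Tomato was 1.3 CPM, where the keratins had 136 CPM. The keratins were set apart because they were lower, and the value compared was changed after it was known, so this contrast cannot exclude such cells. Of the 11, 3 were also lower, namely Epcam (-1.32), Cdh1 (-1.74) and Spint1 (-3.78), and with the replicate block 10 of the 15 were. The injected cells lack the host reporter, though, and both gates would mostly remove them, as the Podoplanin gate would ductal cells. How far the gates did so was not tested. Mesothelial cells, which carry Podoplanin and so can pass the gate, or fibroblasts that keep mesothelial genes, may account for the keratins. Of 12 mesothelial genes 11 were lower in GFP, with Msln at 312 CPM and Upk3b at 276 CPM in Tomato, while Wt1 did not pass. These falls were known before the test was chosen and the list holds the keratin gene Krt14, so they cannot show the source of the keratins. For MHC class II genes, macrophages in the Tomato fraction cannot be told apart from the fibroblasts themselves. How far the Podoplanin gate removed macrophages was not tested, and all 16 macrophage genes tested were lower in GFP. The 6 genes (-4.16) and the macrophage list (-3.31) did not separate (permutation p = 0.1), in a test that takes genes as independent. Dendritic and mesothelial cells stay open as sources too, as the medians of their lists were -2.62 and -4.69.

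Endothelial genes were higher in GFP. Lymphatic endothelial cells carry Podoplanin and pass the gate, and their presence in the GFP fraction stays open. That 7 of 12 genes of the blood endothelial list, which holds genes of all endothelium, were higher along with 6 of 7 lymphatic genes does not argue against it, but these genes are the pattern itself and cannot show its source. The most abundant of these, Mmrn1 and Lyve1, stood at 178 and 108 CPM in GFP. Blood endothelial cells could not be decided by Kdr, at -0.39, which did not pass. Kdr did pass as lower, by edgeR, with library size as the only scaling (-0.56, adjusted p = 0.0434). It also did with the length and GC correction and the block (-0.62, adjusted p = 0.029). Whether Fabp4-Cre was active in lymphatic endothelium was not tested.

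Of 139 matrix genes 68 were higher in GFP and 12 lower. A lower share of fibroblasts in Tomato as the whole of it was examined with 13 common fibroblast genes outside the matrix lists. Fibrillar collagen (median log2 fold change 0.92) exceeded these (0.43, permutation p = 0.0011). That permutation takes genes as independent, while the estimated correlation between genes was 0.43 in the fibrillar collagen and 0.41 in the common fibroblast list. Its p is therefore no measure across libraries and cannot exclude a lower share. With the length and GC correction and the block the medians were 0.52 and 0.42 (permutation p = 0.17), so a lower share of fibroblasts together with transcript length and GC content stays open for fibrillar collagen. For all matrix genes (0.58) the permutation (p = 0.95) cannot decide on a lower share alone. It compares the means of the 2 sets and not whether genes moved alike. Of the matrix genes 68 were higher and 12 lower, and Col1a1 was at 1.30 where the common fibroblast gene Dcn was at -0.10. Transcript length and GC content as the whole of it were examined with the correction and the block. The median of fibrillar collagen, a list fixed beforehand, went from 0.93 to 0.52 (quartiles 0.463 and 0.691 after it). The same 11 genes were higher before and after (camera adjusted p 2.8e-08 and 0.00012). These genes were called in the same libraries, and both p rest on the preset correlation. With an estimated correlation the adjusted p with the block, before the correction, was 0.57. The count of genes and the p therefore cannot count against transcript length and GC content. Basement membrane genes came out differently: their median fell from 0.35 to -0.055 and their call ended (camera adjusted p 0.013 and 0.67). Length bias would give this fall, and so would a real difference between the fractions that follows length. The correction takes out both. The slope of log2 CPM per doubling of length was 0.028 to 0.14 in GFP and -0.147 to -0.024 in Tomato libraries. The fall thus cannot tell them apart. Of the 12 genes higher with the block 11 stayed so after the correction, as did all 4 genes lower. A test over all matrix lists was added after that result was seen, and 80 of the 88 genes higher with the block passed as higher after the correction. These 88 were picked by their call in the same libraries, so many would be kept in any case. Of all 2049 genes called higher with neither block nor correction, 1484 passed as higher with both. Those were picked by another fit than the 88, so the 2 shares are not matched. Because of how the 88 were picked, the test over all matrix lists cannot count against transcript length and GC content. A difference in origin between the fractions, which was not tested here, also stays open.

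The 6 libraries can be split into 3 and 3 in 10 ways, which cannot give a share under 0.05. The real split gave 4505 genes and the highest of the others 1, so 1 split reached the real count, and among the 4 splits that part all pairs of equal number the highest other was 0. For gene lists by camera the real split gave 24 and the highest other 26, with 4 splits at or above the real count and 25 as the highest other among those that part all pairs. The list counts from the preset correlation did not stand apart from those of other splits. Each other split mixes libraries of both fractions, though, so the difference between the fractions stays in it in part and widens the spread within its groups. The splits therefore cannot show how many genes or lists would be called with no difference.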
